A study of Arabidopsis thaliana with 32 samples.

How the data were processed

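Roots of 16-day-old *Arabidopsis thaliana* Columbia-0 plants, grown in hydroponic solution, were profiled 15 min after transfer to fresh solution or to solution holding an osmotic solute. Total RNA from 32 samples was hybridised to one-colour Affymetrix whole-transcript arrays, per the labels. The deposited table held 1 value for each of 28477 probe sets on each array. Normalised expression values made with Affymetrix Expression Console, Transcriptome Analysis Console and GCRMA, a background correction and summary of probe intensities, were deposited by the authors, per the submitters' processing notes, which give no versions. The deposited values ran from 0.2 to 12.45 and were read as log2 from this range, since the log base and any scaling between arrays are not given in the sources used here. If the base were another one, every fold given here would change while the tests would not. The array medians lay between 4.11 and 4.24. The small number of arrays limits the precision.

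Samples were grouped by the solute and dose in their labels, which gave 16 groups of 2 arrays: a control group, NaCl at 25, 50, 75 and 100 mM, sorbitol at 50, 100 and 150 mM, polyethylene glycol 8000 (PEG) at 75, 100, 125 and 150 mM, and ethylene glycol at 50, 100, 150 and 200 mM. The doses are nominal and taken from the labels. For a polymer the size of PEG 8000 the stated molar doses would make very concentrated solutions, so the PEG dose axis is used as labelled and its true scale is open. Nothing in the labels says that the 2 arrays of a group came from separate cultures or plants, so the p-values measure the spread between these samples, part of which may be technical.

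Probe sets were named through the array annotation table, in which 16746 listed 1 gene, 758 listed several and 10973 listed none. Of the first kind, 16601 matched a gene of a current RefSeq table (assembly TAIR10.1, used for names only). No gene was named from a probe set that listed several. Where several probe sets named 1 gene, the one with the highest mean over all arrays was kept, which set aside 192 probe sets. This left 28285 genes for testing, 16554 of them with a name and 11731 known by probe set only. Among all probe sets, 528 held values identical to another on all arrays, and counting these once was an alternative chosen after seeing the data. All 32 columns belonged to a sample, and 0 columns were set aside.

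Tests used limma 3.58.1 in R 4.3.3 on the log2 values, with 1 mean per group, all arrays in the fit, moderated variances with a mean-variance trend, and Benjamini-Hochberg adjustment over all genes tested at 0.05. Each solute was compared with the control as the average over its doses, as a least-squares slope over its doses with the control at 0 mM, given in log2 units per 100 mM, and at each dose alone. Solutes were compared with each other at the doses they share and, for NaCl, also at doses of sorbitol or ethylene glycol with equal nominal osmolarity, counting the pair of ions of NaCl. The ethylene glycol slope was compared with the mean slope of NaCl, sorbitol and PEG. These comparisons, the gene lists, the rule for naming genes and most alternative settings were fixed before the data were examined. Counts at an unadjusted p under 0.05 are given beside many of the calls. With no effect, about 0.05 of the 28285 genes tested would be expected there.

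The sample titles carry numbers from 17 to 32 and from 33 to 48, and each run of numbers holds 1 array of each group; these runs are called the first and the second title-number series, and their arrays replicate 1 and replicate 2. The planned check asked whether arrays of 1 series deviated together from their group means. All 120 pairs of groups showed this, with correlations between 0.501 and 0.767 across genes and a median of 0.672. The series therefore paired the arrays, by a pairing that comes from the title numbers and not from a statement in the labels. The planned fit without the series (16 residual degrees of freedom) and the planned fit with the title-number series as replicate block (15) are both reported. They give the same fold changes and differ in the error, since the median residual SD was 0.272 without the block and 0.190 with it. In the report, SE, adjusted p, "rose", "fell" and "changed" refer to the blocked fit unless the unblocked one is named. Leading with the blocked calls was decided after the counts of both fits had been seen, although the rule for using the block had been fixed earlier.

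Genes were named by a rule. For each average it took the 10 largest rises and 8 largest falls among called genes whose every treated array lay beyond the control. For each slope it took the 3 steepest in each direction, for each contrast between solutes the 5 largest in each direction, and for each list the members with the smallest p. The rule asked for treated arrays beyond both controls, but the 2 series lay so far apart that 6 of the 33 NaCl rises met this, against 24 beyond the control of their own series. The own-series form was therefore used, which was chosen after the values were seen. Genes of the fixed lists and single genes outside the rule are also named, the latter with a statement that they were chosen after their values were seen.

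Of the 26 fixed gene lists, 7 had at least 3 measured members and were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation as an alternative, and with fry, which asks whether a set moves one way on balance. Adjustment ran over the lists within a comparison. A further 6 lists had 1 or 2 measured members and were read member by member: WRKY factors, cytokinin type-A response regulators, reactive oxygen metabolism and root hair markers with 2 each, and DREB and CBF factors and circadian clock with 1 each. The other 13 lists had 0 measured members under the names used here and are not analysed here: ABA receptors, ABA synthesis and signalling, aquaporins, dividing cell markers, endodermis markers, ERF factors, ethylene synthesis, jasmonate synthesis and JAZ genes, MAP kinase cascade, nitrate response, shoot photosynthesis markers, sodium, potassium and proton transport, and xylem markers. Known markers of several root cell types were thus not among the named genes.

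The testing code was run first on simulated data for the NaCl average, where 200 of 28285 genes were changed. The data took each gene's control mean, series difference and residual spread, with independent normal errors. They thus followed the blocked model, so better recovery with the block was built in. With the block, 22.4% of genes changed by log2 0.5 were recovered, 85.1% of those changed by log2 1 and 100% of those changed by log2 2, with 7 false calls. Without the block these shares were 1.49%, 47.8% and 95.5%, with 1 false call. Comparisons that share the control arrays were set beside 100 simulated draws with no effect and beside the overlap of independent lists.

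Alternatives were leaving out genes in the lowest 33.3% by mean signal, quantile normalisation, centring each array on its median, no variance trend, robust variances, fitting the compared groups alone, a minimum fold of 1.5, the mean of a gene's probe sets, and leaving out each array in turn. A group left with 1 array is then assumed to vary like the other groups. Running each of these on the blocked fit, leaving out arrays in the list tests, and slopes over the treated doses alone were added after seeing the data. The result of 1 gene family test is not reported here.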

Results

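The study asked how *Arabidopsis* roots respond within 15 min to changes in turgor and in osmotic potential. Roots were treated with NaCl, sorbitol, polyethylene glycol 8000 (PEG) or ethylene glycol. Ethylene glycol enters plant cells readily, so its osmotic effect on turgor is short-lived, whereas sorbitol and PEG enter far less and NaCl adds ions as well. The data were log2 expression values for 28285 genes on 32 arrays, with 2 arrays for the control and for each of 15 solute and dose groups.

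The largest difference among the arrays followed the 2 title-number series and not the solutes. The first principal component carried 50.4% of the variance and parted the series, and the second carried 5.97%. Arrays of 1 series correlated across genes at 0.981 to 0.994, and arrays of different series at 0.956 to 0.978. Between the series 17759 genes differed in limma, 900 of them by more than 2-fold. On the second component the ethylene glycol arrays lay at 7.66 or above, and the control arrays at 15.1 and 13.3. Other solutes overlapped this range, with NaCl 75 mM replicate 2 at 10.3. PEG at 150 mM, replicate 2, lay farthest out at -36.6. That array also had the narrowest spread of values, an SD of 2.01 log2 units, while control replicate 1 had the widest at 2.22.

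**Figure D1:**
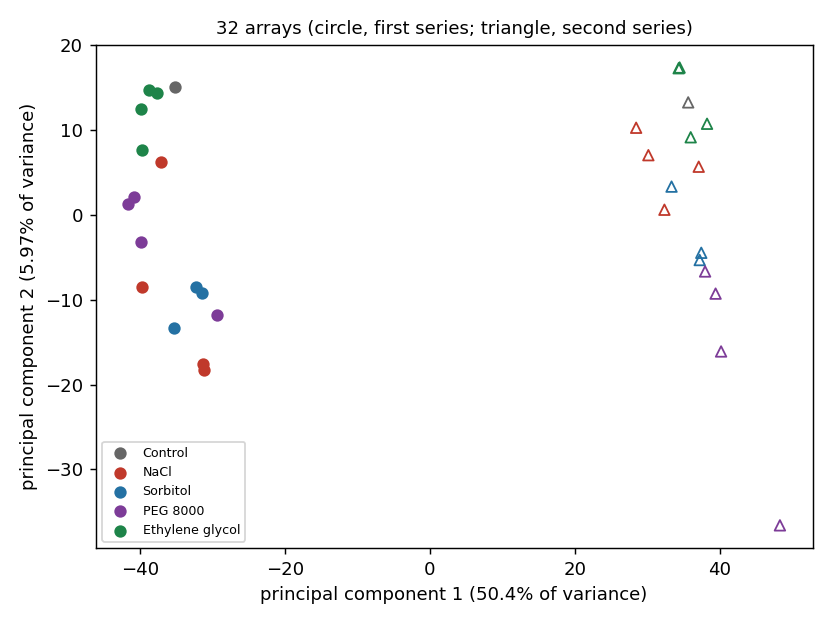
Position of the 32 arrays on the first 2 principal components of the log2 values, coloured by solute and marked by title-number series. The first component (50.4% of the variance) separates the series, and PEG at 150 mM, replicate 2, lies farthest out on the second (5.97%).

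Each dose was first set against the control. With NaCl, 140 genes rose and 26 fell at 100 mM, against 1 and 1 at 25 mM, 2 and 5 at 50 mM, and 28 and 9 at 75 mM. For sorbitol, 91 genes rose and 39 fell at 150 mM, against 1 and 0 at 50 mM and 4 and 4 at 100 mM. For PEG, 107 genes rose and 71 fell at 150 mM, 32 and 23 at 125 mM, 15 and 3 at 100 mM, and 7 and 1 at 75 mM. Ethylene glycol at 200 mM raised 38 genes and lowered 0 (limma; 1350 genes had an unadjusted p under 0.05). At 50, 100 and 150 mM it raised 1, 0 and 1 and lowered 0, with 857, 1008 and 1161 genes at an unadjusted p under 0.05. Each of these counts, and that at 200 mM, is below the share of 0.05 of the 28285 genes tested that chance alone would give. Without the block, limma called 0 genes at each dose of NaCl and ethylene glycol and at sorbitol 50 and 100 mM, with 249 to 828 genes at an unadjusted p under 0.05. It called 3 at sorbitol 150 mM and 1 to 2 at each PEG dose. Each of these comparisons rested on 2 arrays against 2.

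**Figure D2:**
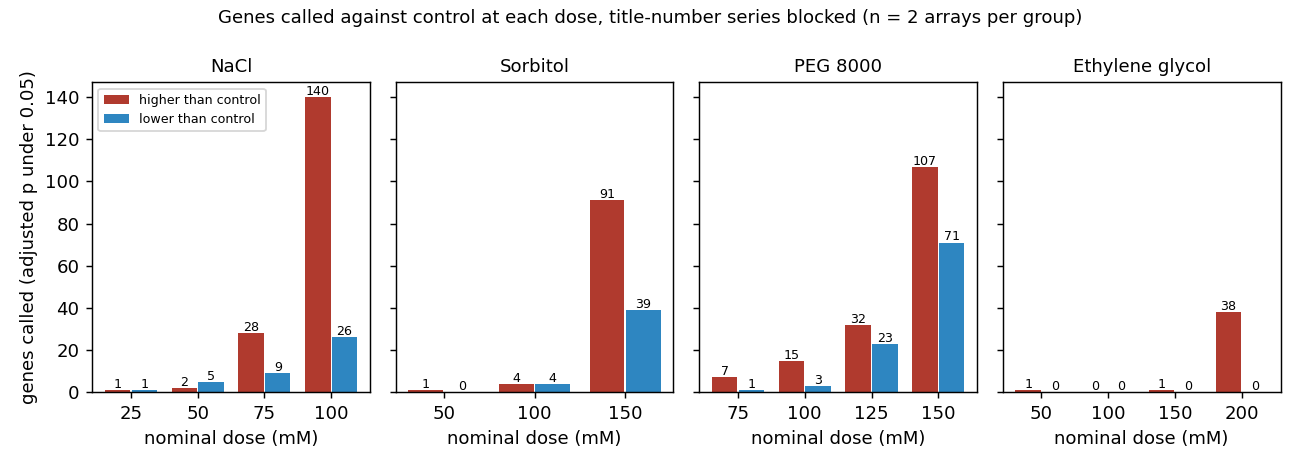
Number of genes higher or lower than the control at each dose in mM, as side-by-side bars of different colour, from the fit with the title-number series as block at an adjusted p under 0.05. The counts are largest at the highest dose of each solute, reaching 140 higher for NaCl, 91 for sorbitol, 107 for PEG and 38 for ethylene glycol, which has 0 lower at every dose.

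The average over NaCl doses was compared with the control to find genes that responded to the salt at any strength. AT3G29000, an EF-hand calcium-binding protein, rose 2.04-fold (log2 1.03, SE 0.13, adjusted p = 0.000427, 8 arrays against 2). AT1G33600, a leucine-rich repeat protein, rose 1.95-fold (log2 0.96, SE 0.17), and the VQ-motif protein AT1G17147 rose 1.73-fold (log2 0.79, SE 0.14). AT1G59865 rose 3.43-fold, with log2 changes of 1.09 in the first series and 2.46 in the second. AT1G76240 fell by 1.02 on the log2 scale (SE 0.15) and AT4G25250, a pectin methylesterase inhibitor, fell by 0.80 (SE 0.14). In all, 33 genes rose and 26 fell, 24 and 9 of them named, whereas limma without the block called 0 (711 at an unadjusted p under 0.05). These calls depended on the control arrays: without control replicate 2 limma called 0 genes (1771 at an unadjusted p under 0.05), and without control replicate 1 25 rose and 12 fell. AT3G29000 and AT1G76240 had adjusted p of 0.192 and 0.349 without control replicate 2, and AT1G33600 (0.114), AT1G17147 (0.0755), AT1G59865 (0.14) and AT4G25250 (0.158) did not pass without control replicate 1. After quantile normalisation 51 rose and 24 fell.

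Sorbitol, averaged over its doses, again raised AT3G29000, 2.24-fold (log2 1.17, SE 0.14, adjusted p = 0.000103, 6 arrays against 2). DLAH, a lipase, rose 1.77-fold (log2 0.82, SE 0.12) and AT4G18250 1.67-fold (log2 0.74, SE 0.11). AT1G76240 fell by 1.3 (SE 0.16), and IQD19, a protein with a calmodulin-binding IQ domain, fell by 0.77 (SE 0.12). Of the 17 genes that rose 8 were named, and of the 22 that fell 10 were named. The unblocked fit in limma called 0 genes, with 897 at an unadjusted p under 0.05. The count was 0 without control replicate 2 (limma; 1987 at an unadjusted p under 0.05), 24 without control replicate 1, 25 without sorbitol 100 mM replicate 2, 24 without sorbitol 150 mM replicate 1 and 21 without sorbitol 50 mM replicate 1. With the second control left out the adjusted p was 0.0545 for AT3G29000, 0.0982 for AT1G76240, 0.153 for DLAH, 0.211 for AT4G18250 and 0.36 for IQD19. The balance turned to rises after centring (23 higher and 19 lower) or quantile normalisation (27 and 16), with the compared groups alone (33 and 24), and without control replicate 1 (15 and 9) or sorbitol 150 mM replicate 1 (13 and 11).

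Under PEG, averaged over its doses, AT1G72540, a protein of the receptor-like kinase family, rose 3.6-fold (log2 1.85, SE 0.21, adjusted p = 1.35e-05, 8 arrays against 2). AT3G29000 rose 2.47-fold (log2 1.3, SE 0.13) and AT1G17147 2.09-fold (log2 1.06, SE 0.14). The probe set 13448869, with no gene name here, rose 2.55-fold (log2 1.35, SE 0.09) and was the 1 gene called without the block (adjusted p = 6.28e-06). AT5G01050, of the laccase family, fell by 0.94 (SE 0.19) and IQD19 fell by 0.81 (SE 0.12). A total of 70 genes rose and 49 fell, 37 and 23 of them named, and without the block 1114 genes had an unadjusted p under 0.05. A fit without control replicate 2 called 7 higher, all among the 70, and 1 lower, not among the 49. A fit without control replicate 1 called 42 and 28, of which 29 and 11 were among them. AT1G72540, AT3G29000 and 13448869 passed with any 1 array left out. Without control replicate 2, AT1G17147 (log2 0.98, adjusted p = 0.0694) and IQD19 (log2 -0.66, adjusted p = 0.195) did not pass, nor did AT5G01050 without either control (0.284 and 0.242). Quantile normalisation gave 103 higher and 41 lower, while the compared groups alone turned the balance, with 67 higher and 90 lower.

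Ethylene glycol, averaged over its doses, raised 2 genes and lowered 0 (limma; 1271 genes at an unadjusted p under 0.05, and 342 without the block, where 0 were called). AT5G40000, of the AAA-type ATPase family, rose 2.12-fold (log2 1.08, SE 0.17, adjusted p = 0.0137, 8 arrays against 2). AT3G29000 rose 1.96-fold (log2 0.97, SE 0.13, adjusted p = 0.00261). For AT5G40000 the other averages were 0.87 under NaCl (adjusted p = 0.0224; 0.349 without control replicate 2 and 0.311 without replicate 1), 0.77 under PEG (0.0368) and 0.64 under sorbitol (0.20). For PEG the call was lost without either control (0.322 and 0.35) and without replicate 1 of PEG 75, 100 or 125 mM (0.0717, 0.071 and 0.0631) or replicate 2 of PEG 150 mM (0.0589). Without control replicate 2 limma called 0 genes for the ethylene glycol average (785 at an unadjusted p under 0.05), with adjusted p of 0.644 for both genes. Without control replicate 1 it called 9 higher and 5 lower, and AT5G40000 did not pass (adjusted p = 0.169).

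The dose slopes asked which genes changed in step with the concentration. Of all genes, 35 rose with the dose of all 4 solutes, 17 of them named. AT3G29000 rose by 1.91 log2 units per 100 mM of NaCl (SE 0.15), 1.51 of sorbitol (SE 0.11), 1.1 of PEG (SE 0.10) and 1.02 of ethylene glycol (SE 0.08), and all 4 calls held with any 1 array left out. AT5G40000 rose by 2.22, 0.73, 0.93 and 0.86 in the same order, and its sorbitol slope alone lost its call, without control replicate 1 (adjusted p = 0.0905), control replicate 2 (0.0696) or sorbitol 150 mM replicate 2 (0.105). The VQ-motif protein AT2G22880 (1.86, 0.95, 0.89 and 0.81), chosen after its values were seen, was also among the 35. Its call was lost without control replicate 2 for sorbitol (adjusted p = 0.108) and PEG (0.173), and without sorbitol 150 mM replicate 1 for sorbitol (0.0521). Of the 49 genes that rose with NaCl, sorbitol and PEG, 35 also rose with ethylene glycol and the other 14 had a positive slope there. All 60 genes that rose with ethylene glycol rose with at least 1 other solute, 55 of them with NaCl. The number rising with all 4 was 3 without control replicate 2, 23 without ethylene glycol 200 mM replicate 1 and 22 without sorbitol 150 mM replicate 1. Over the treated doses alone, without the control, it was also 3.

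**Figure D3:**
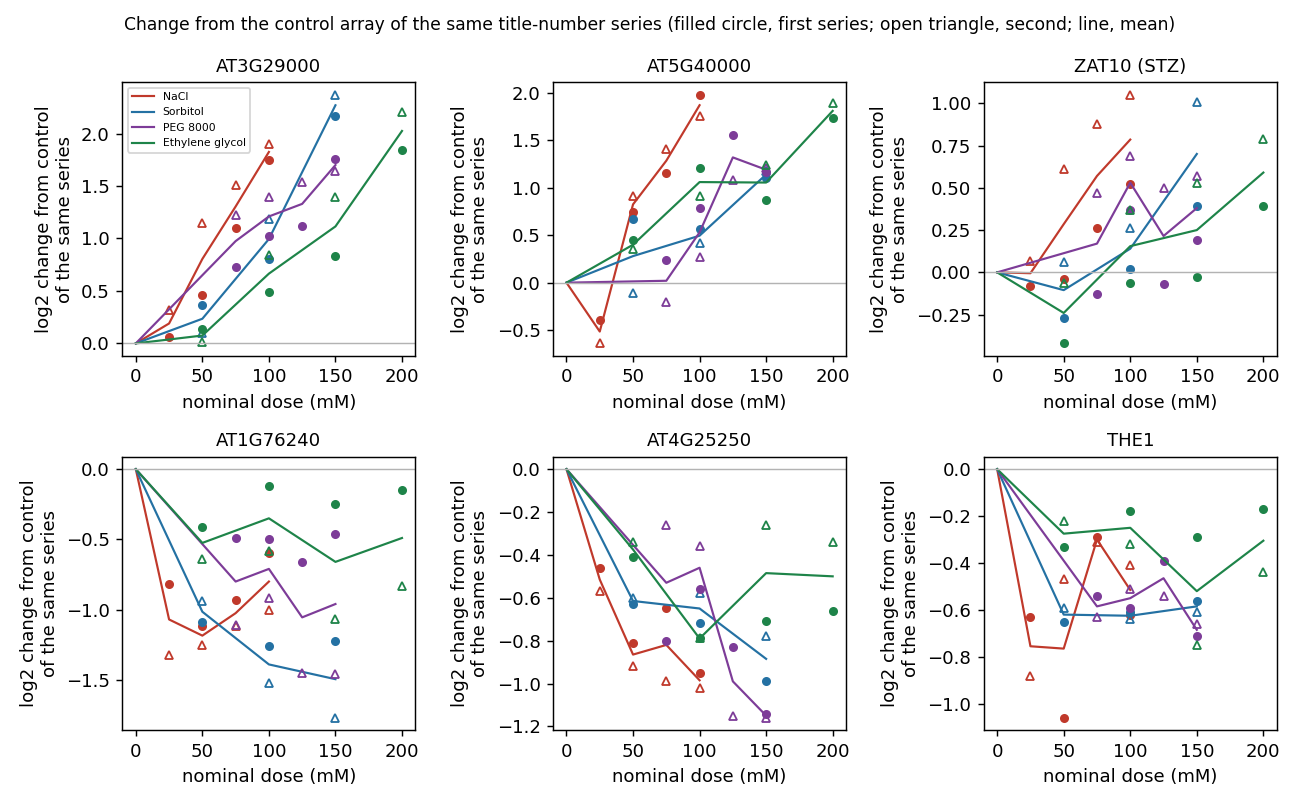
Change in log2 expression from the control of the same title-number series against dose in mM for 6 genes, with a point for each array and a line through the mean of each solute's 2 arrays. AT3G29000 and AT5G40000 rise with each solute, whereas AT1G76240 and AT4G25250 lie lower under NaCl, sorbitol and PEG, with ethylene glycol slopes of smaller size.

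With NaCl dose 252 genes rose and 57 fell, 145 and 24 of them named. AT5G40000 rose steeply (2.22 per 100 mM, SE 0.19, adjusted p = 6.56e-08), and EXPA20, an expansin that loosens cell walls, rose by 1.61 (adjusted p = 4.67e-08) with NaCl dose. ZAT10 (symbol STZ), a zinc finger repressor induced by abiotic stress, rose by 0.86 (SE 0.11), and CML23, a calmodulin-like protein, by 1.40 (SE 0.23). All 4 calls held with any 1 array left out, as did that of probe set 13383152, which fell by 1.25 (SE 0.14). The rule also took probe set 13421994, whose call held too. Its other picks, AT1G59865, AT5G26070 and probe set 13478735, lost their calls in 2, 7 and 1 of 8 such runs. Without the block 8 genes rose and 0 fell, with 894 at an unadjusted p under 0.05. The count was 89 without control replicate 2, 153 without NaCl 100 mM replicate 1 and 188 without NaCl 100 mM replicate 2. Over the treated doses alone 163 genes rose, 145 of them among the 252, and 5 fell, 2 of them among the 57.

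With sorbitol dose 97 genes rose and 38 fell, 48 and 20 of them named. AT3G29000 rose by 1.51 per 100 mM (SE 0.11, adjusted p = 2.10e-09) and AT1G35210 by 1.16 (SE 0.16). AT1G76240 fell by 0.97 (SE 0.12). These 3 calls held with any 1 array left out. The rule also took AT1G59865 (1.44), AT1G28570 (-0.79) and AT1G55430 (-0.78), which lost their calls in 3, 6 and 4 of 8 such runs. Without the block 3 genes rose and 0 fell (816 at an unadjusted p under 0.05), AT1G35210 among them (adjusted p = 0.0392). Leaving out control replicate 2 gave 30 genes, sorbitol 150 mM replicate 1 gave 44 and sorbitol 150 mM replicate 2 gave 67. The treated doses alone gave 41 higher, 34 of them shared, and 1 lower.

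With PEG dose 150 genes rose and 136 fell, 83 and 75 of them named. AT1G72540 rose by 1.38 per 100 mM (SE 0.16, adjusted p = 1.77e-05) and AT5G26070 fell by 1.24 (SE 0.25, adjusted p = 0.0114). The first call held with any 1 array left out, and the second was lost without control replicate 1 (0.111), control replicate 2 (0.161) or PEG 150 mM replicate 2 (0.0588). The median slope of the 136 genes that fell was -0.46. Without the block 4 genes rose and 0 fell, with 1589 at an unadjusted p under 0.05. Leaving out PEG 150 mM replicate 1 gave 887 genes (478 higher, 409 lower), PEG 150 mM replicate 2 gave 121 (92 and 29), control replicate 1 gave 141 (84 and 57) and control replicate 2 gave 27 (19 and 8). Centring gave 192 higher and 109 lower and quantile normalisation 193 and 90, whereas falls outnumbered rises without the dimmest genes (161 and 173) and with the compared groups alone (102 and 128). Over the treated doses alone 7 genes rose and 4 fell.

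With ethylene glycol dose 60 genes rose and 1 fell, 29 and 1 of them named. AT3G29000 (1.02 per 100 mM, SE 0.08, adjusted p = 6.77e-09) and AT5G40000 (0.86, SE 0.10, adjusted p = 2.07e-05) rose in both series, and both passed with any 1 array left out. AT1G49470 was the gene that fell (-0.37, SE 0.08, adjusted p = 0.0449), a call lost without any 1 of its 8 arrays that was left out in turn. With the block 1430 genes had an unadjusted p under 0.05 in limma, near the share of 0.05 of the 28285 genes tested that chance alone would give. Limma without the block called 0 genes (404 at an unadjusted p under 0.05). The count was 11 without control replicate 2 and 32 without ethylene glycol 200 mM replicate 1. Over the treated doses alone 46 rose, 43 of them among the 60, and 0 fell (limma).

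Whether the ethylene glycol slope differed from the mean slope of the other 3 solutes was tested directly, per nominal mM. This sets the permeating solute against the others but does not part uptake from osmolarity. NaCl gives a pair of ions per formula unit, and the scale of the PEG doses is open. In 32 genes the ethylene glycol slope differed. For 15 of them the mean of the others rose more: AT5G11140 had slopes of 1.35, 0.49 and 0.98 per 100 mM of NaCl, sorbitol and PEG and -0.11 of ethylene glycol (difference -1.04, SE 0.16, adjusted p = 0.00370). AT1G33600 differed by -0.73 (SE 0.11, with slopes of 1.64, 0.31, 0.36 and 0.04 in the same order), AT3G02840, with ARM repeats, by -0.65 (SE 0.11) and AT3G29000 by -0.49 (adjusted p = 0.0113). For the other 17 the mean of the others fell more, such as AT1G76240 (difference 0.53, SE 0.10) and the pectin methylesterase inhibitor AT4G25250 (0.51, SE 0.09, with slopes of -0.91, -0.54, -0.76 and -0.22). Without the block 0 genes differed in limma, and 876 had an unadjusted p under 0.05. The count was 17 without control replicate 2, 9 and 3 without ethylene glycol 200 mM replicates 1 and 2, 51 without NaCl 75 mM replicate 1, 50 without PEG 125 mM replicate 1 and 20 without sorbitol 150 mM replicate 1. Without ethylene glycol 200 mM replicate 2, AT4G25250 (adjusted p = 0.156), AT3G02840 (0.0847), AT1G33600, AT1G76240 and AT3G29000 (each 0.0602) did not pass. Without ethylene glycol 200 mM replicate 1 AT5G11140 (0.0548), AT3G02840 (0.0732), AT3G29000 (0.115) and AT1G76240 (0.144) did not, nor did AT3G29000 (0.0694) and AT1G76240 (0.108) without control replicate 2. The balance of 17 higher and 15 lower ethylene glycol slopes turned after centring (16 and 24), quantile normalisation (17 and 47) and with the compared groups alone (19 and 27), and without NaCl 75 mM replicate 1 (21 and 30), control replicate 2 (8 and 9) or ethylene glycol 200 mM replicate 1 (4 and 5) or 2 (1 and 2).

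**Figure D4:**
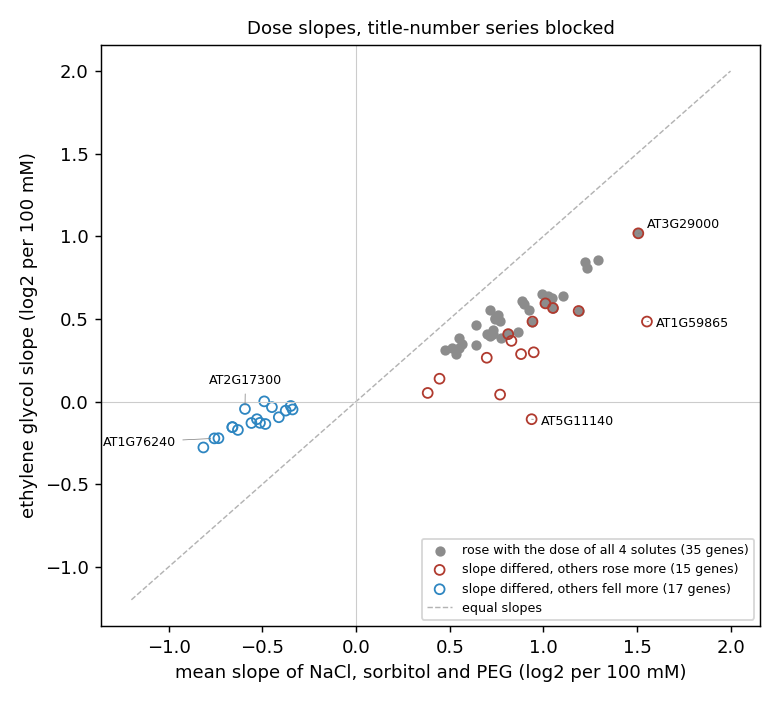
Dose slope under ethylene glycol against the mean dose slope under NaCl, sorbitol and PEG, both in log2 units per 100 mM, with a point for each gene. The 35 genes that rose with all 4 solutes lie in the upper right, and the marked genes whose slopes differed are 15 in which the mean of the other solutes rose more and 17 in which it fell more.

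All solutes were compared with the same 2 control arrays, so their changes correlate even with no effect. The simulations drew errors independently for each gene, so they leave out deviations that an array shares over many genes. Differences from the simulated values thus cannot tell a shared response, or its lack with ethylene glycol, from such deviations. Across genes, which are not independent replicates, the NaCl and sorbitol averages correlated at 0.796, against 0.775 in simulations without effects, NaCl and PEG at 0.745 against 0.801, and sorbitol and PEG at 0.770 against 0.775. Ethylene glycol correlated with NaCl, sorbitol and PEG at 0.690, 0.624 and 0.658, against 0.80, 0.775 and 0.80 simulated. The covariance exceeded the simulated one by 0.00972 for NaCl and sorbitol (0.0311 against 0.0214), by 0.00932 for NaCl and PEG (0.0307 against 0.0213) and by 0.0126 for sorbitol and PEG (0.0339 against 0.0213). With ethylene glycol it exceeded it by 0.000276 for NaCl (0.0216 against 0.0214) and 0.00195 for PEG (0.0233 against 0.0213), and for sorbitol the difference was -0.000411 (0.0209 against 0.0214). For the dose slopes, NaCl and ethylene glycol correlated at 0.526 against 0.40 simulated, with a covariance of 0.0117 against 0.00682. The slopes of sorbitol and ethylene glycol correlated at 0.454 against 0.424 simulated, and those of NaCl and sorbitol at 0.511 against 0.425. NaCl and PEG gave 0.543 against 0.495, and sorbitol and PEG 0.547 against 0.525. For PEG and ethylene glycol the slope correlation was lower than simulated, 0.466 against 0.494. The slope covariance exceeded the simulated one by 0.00804 for NaCl and sorbitol, 0.0113 for NaCl and PEG, 0.00670 for sorbitol and PEG, 0.00161 for sorbitol and ethylene glycol and 0.00235 for PEG and ethylene glycol. Among slope calls NaCl and ethylene glycol shared 55 rises where independent lists would share 0.535, NaCl and sorbitol 69 against 0.864, NaCl and PEG 71 against 1.34, and sorbitol and PEG 58 against 0.514. Part of the excess may come from the shared controls, which are too few to be split with 2 arrays kept on each side.

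NaCl and sorbitol were compared at 50 and 100 mM, where both were used, to set an ionic solute against a sugar alcohol. At equal mM the pair of ions of NaCl gives a higher nominal osmolarity, so ionic and osmotic effects are mixed here. NaCl gave higher levels of AT1G33600 (2.26-fold, log2 1.18, SE 0.15, adjusted p = 0.000317, 4 arrays against 4), the extensin-like leucine-rich repeat protein AT2G15880 (log2 1.3, SE 0.18) and AT3G56790 (log2 1.13, SE 0.14). These 3 passed with any 1 array left out, as did the expansin EXPA20 (log2 0.83), which the rule did not take here. The rule's other genes were less stable. AT2G42395 and AT4G24410 lost their calls in 8 of 8 such runs. AT5G51520 and probe set 13351770 lost theirs in 7, and AT1G59865 and probe set 13458883 in 5. AT3G29000 was 0.70 higher with a 95% interval of 0.46 to 0.94 (adjusted p = 0.00544), which was lost without replicate 2 of NaCl 50 mM (0.0726) or sorbitol 50 mM (0.0667), and AT1G72540 did not pass, with a difference of 0.13 and an interval of -0.26 to 0.51. In all 65 genes were higher with NaCl and 4 lower, 40 and 3 of them named, and without the block limma called 0 (744 at an unadjusted p under 0.05). The count was 38 and 25 without NaCl 100 mM replicates 1 and 2, 38 and 32 without NaCl 50 mM replicates 1 and 2, 41 and 27 without sorbitol 100 mM replicates 1 and 2, and 26 and 35 without sorbitol 50 mM replicates 1 and 2.

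At equal nominal osmolarity, with NaCl at 50 and 75 mM against sorbitol at 100 and 150 mM, 4 genes were higher with NaCl and 0 lower (limma; 1812 at an unadjusted p under 0.05, and 611 without the block, where 0 were called). They were AT2G15880 (log2 1.22, SE 0.18), the expansin EXPA20 (log2 0.87, SE 0.11, adjusted p = 0.000393) and probe sets 13484954 (log2 1.16) and 13484230 (log2 0.86). AT3G29000 did not pass, at -0.58 with an interval of -0.82 to -0.33 (adjusted p = 0.136). EXPA20 passed with any 1 array left out, while AT2G15880 did not without NaCl 50 mM replicate 1 (adjusted p = 0.0511), sorbitol 100 mM replicate 1 (0.0649) or sorbitol 150 mM replicate 1 (0.0677), and each probe set lost its call in 6 of 8 such runs. For 13484954 these were all but NaCl 50 mM replicate 2 and sorbitol 100 mM replicate 1 (adjusted p up to 0.24), and for 13484230 all but NaCl 75 mM and sorbitol 150 mM replicate 2 (up to 0.171). The count was 1 and 12 (4 higher, 8 lower) without NaCl 50 mM replicates 1 and 2, 2 and 8 without NaCl 75 mM replicates 1 and 2, and 2 without sorbitol 150 mM replicate 1. Both scalings gave 4 higher and 2 lower.

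NaCl and PEG shared 75 and 100 mM. NaCl gave higher levels of AT2G15880 (2.93-fold, log2 1.55, SE 0.18, adjusted p = 1.77e-05, 4 arrays against 4), AT5G40000 (log2 1.3, SE 0.15), AT3G56790 (log2 1.2, SE 0.14) and EXPA20 (log2 1.01), and these 4 calls held with any 1 array left out. PEG gave higher levels of probe set 13448869 (difference -1.43, SE 0.08, adjusted p = 2.05e-11), AT1G72540 (-1.05, SE 0.18) and the VQ-motif protein AT1G80450 (-0.97, SE 0.13). In total 77 genes were higher with NaCl and 15 lower, 47 and 3 of them named. Without the block limma called 1 higher and 1 lower (647 at an unadjusted p under 0.05), of which 13448869 was the lower (adjusted p = 3.33e-07). The count was 46 without NaCl 100 mM replicate 2, 52 without PEG 100 mM replicate 1 and 58 without PEG 75 mM replicate 1. AT1G72540 did not pass without NaCl 100 mM replicate 2 (adjusted p = 0.051), NaCl 75 mM replicate 2 (0.0502) or PEG 75 mM replicate 2 (0.0518).

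NaCl and ethylene glycol were compared at 50 and 100 mM and again at equal nominal osmolarity. At matched doses AT1G33600 was 2.46-fold higher with NaCl (log2 1.3, SE 0.15, adjusted p = 5.91e-05, 4 arrays against 4), AT3G29000 was 0.95 higher (adjusted p = 9.05e-05), EXPA20 0.88 higher and ZAT10 (STZ) 0.58 higher (adjusted p = 0.000982), and these 4 calls held with any 1 array left out. A total of 96 genes were higher with NaCl and 30 lower, 57 and 15 of them named. At equal nominal osmolarity 52 were higher and 56 lower, 31 and 25 of them named: AT1G33600 (1.24, SE 0.12) and AT5G11140 (1.31, SE 0.18) were higher with NaCl, and AT3G11385 (-0.72, SE 0.11) and AT5G19190 (-0.68, SE 0.11) lower. The intervals for AT3G29000 (-0.16 to 0.24) and AT5G40000 (-0.24 to 0.27) then included 0. Without the block limma called 0 genes in either comparison, with 1065 and 1222 at an unadjusted p under 0.05. The matched count was 67 and 62 without ethylene glycol 100 mM replicates 1 and 2, 66 and 52 without ethylene glycol 50 mM replicates 1 and 2, and 76 and 77 without NaCl 100 mM replicates 1 and 2. At equal osmolarity it was 63 and 39 without ethylene glycol 100 mM replicates 1 and 2, 33 and 56 without ethylene glycol 150 mM replicates 1 and 2, 58 and 40 without ethylene glycol 200 mM replicates 1 and 2, and 45, 41 and 59 without replicate 1 of NaCl 100, 50 and 75 mM. The split at equal osmolarity turned, to 77 and 44 after centring, 88 and 39 after quantile normalisation and 85 and 56 with the compared groups alone. It also turned without ethylene glycol 150 mM replicate 1 (18 and 15), ethylene glycol 200 mM replicate 1 (31 and 27) or 2 (23 and 17), or replicate 1 of NaCl 100 mM (25 and 20), 50 mM (23 and 18) or 75 mM (42 and 17).

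Sorbitol and PEG, a small and a polymeric solute, shared 100 and 150 mM and differed in 22 genes, 7 higher with sorbitol and 15 lower, 1 and 6 of them named. Probe set 13448869 was lower with sorbitol by -1.71 (SE 0.08, adjusted p = 2.51e-13, 4 arrays against 4) and was the 1 gene called without the block (857 at an unadjusted p under 0.05). AT1G72540 was lower by -1.15 (SE 0.18, adjusted p = 0.00671), a call lost without sorbitol 100 mM replicate 2 (adjusted p = 0.0543). AT3G29000 did not pass, with a difference of 0.18 and an interval of -0.07 to 0.42. The balance turned without PEG 150 mM replicate 1 (33 higher and 25 lower) and with the compared groups alone (47 and 16). The count was 5 without PEG 100 mM replicate 1, 58 without PEG 150 mM replicate 1, 10 and 12 without sorbitol 100 mM replicates 1 and 2, and 14 without sorbitol 150 mM replicate 1.

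Sorbitol was set against ethylene glycol at 50, 100 and 150 mM, which compares 2 uncharged small solutes of different uptake. AT3G29000 was 0.55 higher with sorbitol (adjusted p = 0.0120, 6 arrays against 6), a call lost without ethylene glycol 150 mM replicate 1 (0.0699), ethylene glycol 50 mM replicate 2 (0.0631) or sorbitol 150 mM replicate 1 (0.0511). Probe set 13351770 was 0.96 higher (SE 0.13). AT3G11385 (-0.95, SE 0.11, adjusted p = 0.000178), AT1G76240 (-0.79, SE 0.11) and AT5G19190 (-0.78, SE 0.10) were lower with sorbitol, and these calls and that of 13351770 held with any 1 array left out. In all 40 genes were higher and 49 lower, 22 and 24 of them named, and AT3G11385 was the 1 gene called without the block (adjusted p = 0.0391; 1796 at an unadjusted p under 0.05). The count was 29 and 27 without ethylene glycol 100 mM replicates 1 and 2, 14 and 40 without ethylene glycol 150 mM, 25 and 21 without ethylene glycol 50 mM, 50 and 44 without sorbitol 100 mM, 20 and 134 without sorbitol 150 mM, and 48 and 41 without sorbitol 50 mM, in the same order of replicates. The balance turned after centring (58 higher and 27 lower) or quantile normalisation (27 and 23), without a variance trend (24 and 21) and at a minimum fold of 1.5 (19 and 12).

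PEG and ethylene glycol shared 100 and 150 mM. AT5G11140 was 3.1-fold higher with PEG (log2 1.63, SE 0.22, adjusted p = 0.000382, 4 arrays against 4), AT1G72540 2.22-fold (log2 1.15, SE 0.18) and probe set 13448869 2.79-fold (log2 1.48, SE 0.08), and these 3 calls held with any 1 array left out. AT3G29000 was 0.57 higher (adjusted p = 0.0497), a call lost when any of the 8 arrays but PEG 150 mM replicate 2 was left out (up to 0.188). A total of 29 genes were higher and 8 lower, 14 and 3 of them named, and without the block limma called 2 higher and 0 lower (1607 at an unadjusted p under 0.05). The count was 15 and 14 without ethylene glycol 150 mM replicates 1 and 2 and 720 without PEG 150 mM replicate 1 (452 higher, 268 lower). Centring gave 59 higher and 5 lower, and quantile normalisation 53 and 5.

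Among the fixed lists, the wall-loosening genes, which encode xyloglucan-modifying XTH enzymes and expansins, were lower as a group under PEG. The median over the 8 members was -0.31 for the PEG average (camera adjusted p = 0.000593; adjusted p = 0.0312 with an estimated correlation) and -0.26 per 100 mM for the PEG slope (0.00118; 0.0419 with an estimated correlation). The camera call held for both with any 1 array left out. With the estimated correlation the average lost its call without control replicate 2 (adjusted p = 0.11), PEG 125 mM replicate 2 (0.0513) or PEG 75 mM replicate 1 (0.0544). The slope lost it without control replicate 2 (0.106), PEG 150 mM replicate 1 (0.0526) or 2 (0.0693), replicate 2 of PEG 125 mM (0.0818) or 75 mM (0.0571), or PEG 100 mM replicate 1 (0.0505). Adjusted over the list alone, 4 of 8 members fell in each, against 0 over all genes: XTH16 (-0.59), EXPA7 (-0.43), XTH21 (-0.38) and EXPA18 (-0.38) in the average. The expansin EXPA20, which the list did not hold, went the other way: it rose with NaCl dose (1.61) and ethylene glycol dose (0.47) and in the NaCl average (0.80), the last call lost without control replicate 2 (adjusted p = 0.25). EXPA7 and EXPA18 are also the 2 root hair markers measured, and both fell adjusted over that list alone (adjusted p = 0.0115). With the estimated correlation the list's call was lost for NaCl (camera adjusted p = 0.0150; adjusted p = 0.0988), sorbitol (0.0198; 0.0764) and ethylene glycol (0.0118; 0.0612) averages and for the sorbitol slope (0.0312; 0.123). Adjusted over the list alone XTH16 and XTH21 fell in the NaCl and sorbitol averages, and 0 of 8 members passed for ethylene glycol. Without control replicate 2 the camera adjusted p was 0.171, 0.224 and 0.192 for these 3 averages.

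The C2H2 zinc finger stress factors, 4 genes with ZAT10 (STZ) among them, rose as a group with ethylene glycol dose (median 0.17 per 100 mM, camera adjusted p = 0.000891; adjusted p = 0.0102 with an estimated correlation), a camera call that held with any 1 array left out, while with the estimated correlation it was lost without control replicate 1 (0.0623). ZAT10 rose by 0.33 (adjusted p = 0.00217) and ZAT7 by 0.23 adjusted over the list alone, so 2 of 4 rose there and 1 of 4 over all genes. With sorbitol dose the median was 0.23 (0.0152; adjusted p = 0.0499 with an estimated correlation), with 2 of 4 members rising adjusted over the list alone and ZAT10 (0.47) over all genes; without sorbitol 150 mM replicate 2 the camera adjusted p was 0.15 and that of ZAT10 0.0678. With the estimated correlation the sorbitol call was lost when any of the 8 arrays but sorbitol 150 mM replicate 1 was left out (up to 0.295). Without control replicate 2 ZAT10 did not pass for sorbitol (adjusted p = 0.183) or ethylene glycol (0.202). For the averages the call was lost with an estimated correlation for NaCl (camera adjusted p = 0.0150; adjusted p = 0.0549), sorbitol (0.0286; 0.0764), PEG (0.0415; 0.0703) and ethylene glycol (0.0252; 0.0612). ZAT10 was higher with NaCl than with sorbitol at matched doses (0.52, adjusted p = 0.00516), which was lost without NaCl 100 mM replicate 2 (0.05), NaCl 50 mM replicate 2 (0.0576) or sorbitol 100 mM replicate 2 (0.0576).

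The 5 touch and calmodulin-like genes rose as a group with NaCl dose (median 0.24 per 100 mM, camera adjusted p = 0.00350; adjusted p = 0.0463 with an estimated correlation). Of these CML23 rose, both over all genes (1.40, adjusted p = 0.00103) and adjusted over the list alone, and the other 4 did not pass. The list's camera adjusted p was 0.0546 without control replicate 2. With the estimated correlation the call was lost without that array (adjusted p = 0.124), NaCl 100 mM replicate 1 (0.135) or 2 (0.0956), NaCl 25 mM replicate 1 (0.0896) or 2 (0.0535), or NaCl 75 mM replicate 2 (0.103). For NaCl against sorbitol at matched doses the call (0.00608) was lost with an estimated correlation (adjusted p = 0.0611) and without sorbitol 100 mM replicate 1 (0.15) or sorbitol 50 mM replicate 1 (0.123). There 0 of 5 members passed over all genes and 2 adjusted over the list alone, CML23 (0.76) and AT1G76640 (0.59). CML37 rose with sorbitol dose (0.60, adjusted p = 0.0413), which was lost when any of the 8 arrays but sorbitol 50 mM replicate 2 was left out (up to 0.505).

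Among the 3 mechanosensitive and osmosensing genes, THE1, a receptor kinase that monitors the cell wall, fell by 0.58 under NaCl, by 0.61 under sorbitol and by 0.57 under PEG on average (adjusted p = 0.0362, 0.0434 and 0.0276), and its change under ethylene glycol was -0.34 (adjusted p = 0.959). FER and AT2G48060 did not pass in these averages, over all genes or adjusted over the list alone. The list was called lower for the sorbitol average (camera adjusted p = 0.0191) and PEG average (0.0359) and the sorbitol (0.0312) and PEG (0.0338) slopes, all lost with an estimated correlation (adjusted p = 0.0764, 0.0703, 0.102 and 0.102). THE1 lost its call for NaCl without control replicate 1 (adjusted p = 0.258) or 2 (0.456), NaCl 100 mM replicate 1 (0.0775), 25 mM replicate 2 (0.0719) or 75 mM replicate 1 (0.0501) or 2 (0.0547). For sorbitol it was lost without any 1 of the 8 arrays (0.0725 to 0.435), and for PEG without control replicate 1 (0.198) or 2 (0.423) or PEG 100 mM replicate 1 (0.0532).

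The auxin-responsive genes (8 members), heat shock genes (3) and osmotic and ABA-regulated protective genes (4) were called in none of the 17 comparisons, with smallest camera adjusted p of 0.283, 0.283 and 0.189. Adjusted over the list alone LBD29 was higher with NaCl than PEG (0.58) and COR47, a dehydrin, fell with PEG dose (-0.17), against 0 members over all genes. In the lists of 1 or 2 members, WRKY6 was higher with NaCl than ethylene glycol at equal nominal osmolarity over all genes (0.33, adjusted p = 0.0422), a call lost when any of the 12 arrays but NaCl 75 mM replicate 1 was left out (up to 0.132). Adjusted over each list alone, WRKY22 (0.44) and WRKY6 (0.30) rose with NaCl dose, the cytokinin response regulator ARR15 fell in the NaCl average (-0.51), GSTU25 rose in the PEG average (0.55) and DREB2C fell with sorbitol dose (-0.29). That adjustment covers 1 or 2 genes and not the 17 comparisons, so passes by chance are to be expected among these. GI, the 1 circadian clock gene measured, passed in none of the comparisons. Of 119 list tests, camera without the block called 7, of which 2 held with an estimated correlation, and with the block 18, of which 5 held.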

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

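The tests of one array, of quantile normalisation, of the controls and of permuted doses were all chosen after the calls they bear on had been seen, and for the first 3 related counts had been seen too. The bounds that decide each were written before the deciding value was computed. Setting the splits of the blocked fit against series-balanced ones, and reading nothing from a lead of 1 gene, were chosen after their counts were seen.

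In 17 genes the ethylene glycol slope was higher than the mean slope of the other solutes, and in 15 it was lower (limma with the block). This is a difference per nominal mM from a mean of 3 slopes, and a steep NaCl slope carries most of it in some genes, such as AT1G33600 (1.64 for NaCl, 0.31 for sorbitol, 0.36 for PEG and 0.04 for ethylene glycol). In 1 gene, AT5G35735, the NaCl average differed between the title-number series, -0.12 in the first and 0.97 in the second (difference 1.09, limma adjusted p = 0.0146). For sorbitol, PEG and ethylene glycol 0 genes differed between the series in limma, with 1512, 1914 and 1410 at an unadjusted p under 0.05. For NaCl 2015 genes did so. All of these counts but that for ethylene glycol lie above 0.05 of the 28285 genes tested. With 11 residual degrees of freedom, few calls do not show that the solutes act alike in both series, as the block assumes.

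With PEG dose 136 genes fell, against 57 with NaCl and 38 with sorbitol, but this order turned without PEG 150 mM replicate 2 (29 for PEG), without control replicate 2 (8 against 9 and 9) and over the treated doses alone (4 for PEG and 5 for NaCl), while without PEG 150 mM replicate 1 409 fell. Without PEG 150 mM replicate 2, the array farthest from the rest, 27 of the 136 remained called, with 1 array fewer behind each slope, but the median slope of all 136 went from -0.46 (interquartile range 0.176) to -0.43 (0.191), a ratio of 0.930. The genes were chosen with that array included, and other arrays, chiefly the controls, carry most of the weight in these slopes. The ratio could therefore hardly have been small, and it decides nothing about that array. After quantile normalisation 78 remained called and the median was -0.41 (0.193), a ratio of 0.896, so the array-wide spread of values is not the whole cause of these slopes. Still open are PEG 150 mM replicate 2, the 2 control arrays, which every slope uses, and the true concentrations of PEG. A lowering of transcripts by PEG may underlie the pattern, as a hypothesis that these tests leave untested.

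Without control replicate 2 the averages called 0 genes for NaCl, sorbitol and ethylene glycol and 8 for PEG in limma. Against control replicate 2 alone 145 calls were made over the 4 averages, a gene counting once for each average that called it, and in 130 of them the gene moved the same way against control replicate 1 within the first series. The median change there was 0.33 (interquartile range 0.43) against 0.93 in the second series, a ratio of 0.359 that lies between the bounds set for a peculiarity of that array and for a change shared by the series. The treated arrays of the first series entered the choice of genes, so the shared direction is not independent of it. A peculiarity of control replicate 2 and a true response measured with few controls cannot be told apart here, since only 2 control arrays exist to decide it.

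Of the 252 genes that rose with NaCl dose 55 also rose with ethylene glycol dose, and both slopes use the same controls. When both slopes were taken over treated doses alone, which share no array, 137 genes rose in a fit of the NaCl arrays alone (163 in the fit of all arrays) and 133 of them had a positive ethylene glycol slope. Their median slope was 0.394 per 100 mM, and no permutation of the ethylene glycol doses within the series reached it (highest 0.386; one-sided exact permutation p = 0.00174, the smallest that 576 permutations can give). These slopes hold no control array, so the controls could not cause them, whatever the permutation gave. The permutation bears on the order of the ethylene glycol doses. How far the shared controls add to the 55 shared calls, whose slopes use them, is left open. A response common to the ionic and the permeating solute is consistent with these values as a hypothesis, while handling that ran alongside dose in both solutes was not tested.

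Other splits of the same arrays into groups of the same sizes were fitted with the doses pooled. With the block, and since the series pairs the arrays, the real split is set against those that take as many arrays from each series. For sorbitol against ethylene glycol the real split gave 213 genes (highest other 28, 1 of 60 such splits drawn). For NaCl against ethylene glycol at equal nominal osmolarity it gave 177 (2, 1 of 49 drawn). The other splits could part the 2 arrays of a group, which the real split keeps together. Any difference between groups thus favours the real split, and chance is not excluded. For the other 6 comparisons such splits number 18, too few for a share under 0.05. There the real split gave 3 genes for NaCl against sorbitol (highest other 0), 112 for NaCl against PEG (22), 27 for NaCl against ethylene glycol (3), 44 for sorbitol against PEG (2), 29 for PEG against ethylene glycol (1) and 2 for NaCl against sorbitol at equal nominal osmolarity (3, 2 of 18 as large).

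Without the block the real split gave 1 gene for sorbitol against ethylene glycol (highest other 0, 1 of 100 drawn). A lead of 1 gene decides nothing, and in the fit of all groups the 1 call went to 0 after centring or quantile normalisation and with the compared groups alone. For the rest the real split gave 0 genes for NaCl against sorbitol (35 of 35 as large), 2 for NaCl against PEG (2 of 35), 0 for NaCl against ethylene glycol (35 of 35), 1 for sorbitol against PEG (2 of 35), 1 for PEG against ethylene glycol (2 of 35), and at equal nominal osmolarity 1 for NaCl against sorbitol (2 of 35) and 0 for NaCl against ethylene glycol (100 of 100 drawn, highest other 1). In 6 of these the highest other split is the one along the title-number series, with 9097, 9580, 9258, 9794, 10409 and 8928 genes, which points to a structure of the samples; without it the series-balanced others gave 0 (limma).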

How the results depend on the processing

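Slopes over treated doses alone, every alternative run with the series as block, and leaving out arrays in the list tests were chosen after seeing the data. Counts below are genes called in limma, or tests called in camera, and unless said otherwise the cause of a changed count was not tested.

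Of the 173 results for named genes, all taken from calls in these same data, 0 reversed under any alternative. Leaving out the block, other variance settings and a minimum fold keep the fold changes, so these results could not reverse there. They stayed past the threshold in 163 after quantile normalisation, 164 after centring, 154 with robust variances, 123 without a variance trend, 143 with the compared groups alone, 158 at a minimum fold of 1.5 and 168 with the mean of probe sets, and lost the call in 10, 9, 19, 50, 30, 15 and 5. With 1 array left out 1262 of these results stayed past the threshold and 500 did not, with fewer samples in each fit. Without the replicate block 8 stayed and 165 did not. Over the treated doses alone 12 of the slope results stayed and 16 did not. The number of arrays limits the precision. Signal over background was not used here, and leaving out the dimmest genes kept the call of 169 results.

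Adding the title-number series as replicate block moved every count of genes called by over 1.5 times, to 59 for the NaCl average, 39 for sorbitol, 119 for PEG and 2 for ethylene glycol. The slopes went to 309 (NaCl), 135 (sorbitol), 286 (PEG) and 61 (ethylene glycol). The matched contrasts went to 69 (NaCl against sorbitol), 92 (NaCl against PEG), 126 (NaCl against ethylene glycol), 22 (sorbitol against PEG), 89 (sorbitol against ethylene glycol) and 37 (PEG against ethylene glycol), and those at equal nominal osmolarity to 4 (NaCl against sorbitol) and 108 (NaCl against ethylene glycol). The block gave 32 genes for the ethylene glycol slope against the others, 35 genes rising with all 4 solutes and 18 list tests. The block removed the difference between the series from the residual, which lowered the median residual SD from 0.272 to 0.190, and in the comparisons between solutes, averages and slopes all genes called without the block were also called with it.

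Without the block, leaving out dim genes gave 2 for the PEG average, 13 for the NaCl slope and 2 for the ethylene glycol slope. The compared groups alone gave 0 for the PEG average, for the NaCl, sorbitol and PEG slopes, and for NaCl against PEG, sorbitol against PEG, sorbitol against ethylene glycol and PEG against ethylene glycol. No variance trend gave 2 for the PEG average. Quantile normalisation gave 13 for the NaCl slope, 5 for NaCl against PEG and 0 for sorbitol against ethylene glycol, and centring 5 and 0 for the last 2. The treated doses alone gave 1 for the NaCl slope and 0 for sorbitol and PEG. An estimated correlation left 2 list tests. With 1 array left out the ranges were 1 to 2 for the PEG average, 0 to 13, 0 to 2 and 1 to 10 for the NaCl, sorbitol and PEG slopes, 1 to 3 for NaCl against PEG, 0 to 1 for NaCl against ethylene glycol, 1 to 2 for sorbitol against PEG, 0 to 1 for sorbitol against ethylene glycol, 1 to 7 for PEG against ethylene glycol and 0 to 1 for the ethylene glycol slope against the others.

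With the block, no variance trend gave 22 for the NaCl average, 12 for sorbitol and 62 for PEG, 142 for the PEG slope, 30 for NaCl against sorbitol, 76 for NaCl against ethylene glycol and 27 at equal nominal osmolarity, 45 for sorbitol against ethylene glycol, 22 for PEG against ethylene glycol, 10 for the ethylene glycol slope against the others and 22 for genes rising with all 4. The compared groups alone gave 30 for the NaCl average, 105 for the ethylene glycol slope, 63 for sorbitol against PEG and 178 for sorbitol against ethylene glycol. A minimum fold of 1.5, which can only remove calls, gave 56, 95 and 14 for the sorbitol, PEG and ethylene glycol slopes, 45 for NaCl against sorbitol, 75 for NaCl against ethylene glycol and 29 at equal nominal osmolarity, 31 for sorbitol against ethylene glycol, 6 for the ethylene glycol slope against the others and 8 for genes rising with all 4. The treated doses alone, with fewer arrays and a shorter dose range, gave 168, 42 and 11 for the NaCl, sorbitol and PEG slopes and 3 for genes rising with all 4. Quantile normalisation gave 39 for sorbitol against PEG, 50 for sorbitol against ethylene glycol, 58 for PEG against ethylene glycol and 64 for the ethylene glycol slope against the others, and centring 64 for PEG against ethylene glycol. Leaving out dim genes gave 58 for PEG against ethylene glycol, 169 for NaCl against ethylene glycol at equal nominal osmolarity and 54 for the ethylene glycol slope against the others. An estimated correlation left 5 list tests.

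With the block and 1 array left out, the averages ranged from 0 to 61 (NaCl), 0 to 33 (sorbitol), 8 to 160 (PEG) and 0 to 14 (ethylene glycol), and the slopes from 89 to 311 (NaCl), 30 to 115 (sorbitol), 27 to 887 (PEG) and 11 to 72 (ethylene glycol). The matched contrasts ranged from 25 to 41 (NaCl against sorbitol), 46 to 86 (NaCl against PEG), 52 to 141 (NaCl against ethylene glycol), 5 to 58 (sorbitol against PEG), 14 to 134 (sorbitol against ethylene glycol) and 14 to 720 (PEG against ethylene glycol). At equal nominal osmolarity they ranged from 1 to 12 (NaCl against sorbitol) and 33 to 134 (NaCl against ethylene glycol). The ethylene glycol slope against the others ranged from 3 to 51 and genes rising with all 4 from 3 to 40.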

Other observations

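The family tests and the genes in this part were chosen after seeing the data.

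Families of genes sharing a symbol stem, and the plastid genome, were tested with camera in the blocked fit, 57 families of at least 5 members in 17 comparisons, some of them partly held by a fixed list, as WRKY and XTH were. The 7 WRKY genes with a name were higher with NaCl than with ethylene glycol at equal nominal osmolarity (median 0.22, camera adjusted p = 0.0426), 2 of them past the threshold over all genes, and the call was lost with an estimated correlation (adjusted p = 0.461). The 10 PUB genes, of the U-box ubiquitin ligase family, were higher with NaCl than with ethylene glycol at matched doses (median 0.24, camera adjusted p = 0.0161; adjusted p = 0.150 with an estimated correlation), with 1 of them past the threshold. The 9 XTH genes, which remodel wall xyloglucan, were lower in the PEG average (median -0.23, camera adjusted p = 0.0237; adjusted p = 0.648 with an estimated correlation), with 0 past the threshold over all genes in limma.

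The 63 genes of the plastid genome were lower with NaCl than with ethylene glycol at equal nominal osmolarity (median -0.16, camera adjusted p = 6.77e-22), with 1 gene past the threshold over all genes. They were also lower with sorbitol (median -0.14) and PEG (-0.12) than with ethylene glycol at matched doses. Their estimated inter-gene correlation was 0.473, and with it all 3 calls were lost (adjusted p = 0.530, 0.587 and 0.588). The LCR family of small cysteine-rich proteins (63 genes) was higher with PEG (median 0.14) and with sorbitol (0.14) than with ethylene glycol at matched doses, higher with NaCl at equal nominal osmolarity (0.09), and higher with PEG dose (0.07). All 4 calls were lost with an estimated correlation (adjusted p = 0.289, 0.403, 0.570 and 0.609).

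Between the title-number series, the named genes with the largest difference were AT2G30660 (second minus first -3.80), AT1G13310 (-3.35), AT1G65481 (-3.19) and PUB54 (-3.18), each beyond any average or slope given in the report.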
